A study of Homo sapiens with 80 samples.

How the data were processed

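The authors deposited 5 tables in RPM (reads per 1000000 reads), 1 each for miRNAs, tRNAs, piRNAs, other annotated genes and circular RNAs, with 1 column per library. The deposited tables carry the name of the exceRpt small RNA pipeline, whose version is not given in the sources used here. The genome build is hg19, per the submitters' processing notes. The deposited RPM values of a library sum to 22.57% to 99.8% of 1000000 over the 5 tables, so the denominator includes reads outside them. RPM is a share, so a class that takes many reads lowers the RPM of every other class. The number of columns used was 80 per table.

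Libraries were grouped by the set in their titles (B33, B35, B36 and B37) and numbered by the adapter number in the title, which stood for the same 3′ adapter in all sets, with 24 adapters in all. For each library the largest RPM step was sought of which at least 89% of its miRNA values were whole multiples, within 0.001 reads. It was taken as 1 read, and 1000000 divided by it as the library's reads. Between 89.2% and 100% of a library's miRNA values were whole, with a median of 92.0%. In 68 libraries at least 95% of the low values were whole multiples of 1 step. The count test was run on those libraries only, with the remaining fractions of a read rounded. For the other 12 the depth is less certain. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The detection limit was 3 reads.

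Tests were run on log2(RPM + 1) with limma 3.58.1 in R 4.3.3 (linear model over the 4 sets, empirical Bayes with a mean-variance trend), on features with an RPM of 10 or more in at least 11 libraries: 371 miRNAs, 24 tRNA rows, 19 piRNAs and 469 gene rows. Fold changes are on the log2(RPM + 1) scale and understate the change of low features. p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A moderated F-test compared the 4 sets, and contrasts compared B37 with the mean of the other sets and the same-stem sets with each other. Lists were tested with camera (correlation 0.01, and again estimated) and fry. Correlations used 100000 permutations, two-sided; 1 of the 5 pairs computed is not reported here. edgeR 4.0.16 (TMM factors, quasi-likelihood test) was run on the recovered reads. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

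The test was tried on simulated data with 200 changed features, drawn with the spread and depths of the real libraries. Each feature was drawn independently of the others. For miRNAs in B37 against the other sets (371 features), 34% of 4-fold and 10% of 2-fold changes were called and 0 of 171 unchanged features. For gene rows (469 features), 26% of 4-fold and 3% of 2-fold changes were called and 0 of 269 unchanged. In this simulation most changes of these sizes were missed, so many may be missed in the real data. Counting noise was added to a spread that already holds it, which can lower the share called. The 0 calls of unchanged features do not bound false calls here. Random splits of the real libraries into sets of the same sizes called up to 87 miRNAs and 114 gene rows in this contrast.

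The rule for named features, the lists, the tests and most alternatives were fixed before the data were examined. Named were the 20 miRNAs, 10 tRNA rows, 5 piRNAs and 20 protein-coding rows with the highest mean of the 4 set means, the 10 largest rises and 10 largest falls in B37 with the same sign against each other set (5 for tRNA and piRNA), the 5 miRNAs with the lowest F-test p, and members of the fixed lists. Alternatives were other pseudocounts (0.1 and 10), no filter or a filter of 40 libraries, 3 other scalings, the adapter number as a block, no trend, library weights and leaving out a set. Left out of every table were X-inactivation transcripts, genes on the Y chromosome, genes with a common deletion genotype and genes of sex-specific tissues, which removed 475 of 58427 gene rows and 5 of 532 piRNA rows. Where a gene lies was taken from GENCODE 29 and RefSeq for this step only, and no coordinates are given since their build differs. Circular RNAs had no row that passed the filter and were not tested. No 2 libraries held identical miRNA values, and the highest Spearman correlation between libraries was 0.937.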

Results

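Cell-free small RNA was sequenced from 80 urine samples of people with nephrotic syndrome, a condition in which the glomerular filter of the kidney leaks plasma protein into the urine. The labels gave this condition for every sample and no diagnosis or stage per sample, and no samples from people without it were among those used here. The labelled split was the title set: 23 libraries each in B33, B35 and B36, whose titles share a stem, and 11 in B37, whose titles carry a longer stem. The longer stem adds the words CTOT and Progress, which the labels do not explain. Values were deposited as RPM, reads per 1000000 reads, for miRNAs, tRNAs, piRNAs, other annotated genes and circular RNAs. The smallest step between RPM values gave the reads per library, which ran from 1150 to 58931286 with a median of 407063. miRNA reads ran from 428 to 5923428, and 19 libraries held fewer than 100000 reads in all. At the median depth, 3 reads corresponded to 7.37 RPM. Depth also differed by set, with median reads of 144401 in B33, 515555 in B35, 548273 in B36 and 262761 in B37. Libraries under 100000 reads numbered 10, 5, 1 and 3 in the same order. At the median depth of each set, 3 reads corresponded to 20.8, 5.82, 5.47 and 11.4 RPM. Differences of low features between sets may therefore reflect depth. The labels do not say that samples come from separate people, so p-values measure the spread between these samples.

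miRNAs and tRNA fragments made up most of the urine small RNA. miRNAs held 41.9% ± 26.2 of reads (SD, n = 80) and tRNAs 40.5% ± 31.0. A single isotype, tRNA-Gly, held 34.4% ± 32.0, with a median of 20.7% and a range of 0.57% to 95.9%, and tRNA-Glu followed with 3.4% ± 2.6. The other annotated genes held 5.9% ± 4.2 and piRNAs 0.3% ± 0.2. miRNA exceeded tRNA in 44 of 80 libraries, and tRNA-Gly passed 500000 RPM in 27. The miRNA share fell as the tRNA-Gly share rose, with Pearson r = -0.82 and Spearman rho = -0.8 (n = 80; permutation p = 1e-05 for both, the smallest the permutations can give; adjusted p = 2e-05 over 2 relations). Within sets, r was -0.85 in B33, -0.77 in B35, -0.78 in B36 and -0.93 in B37, and without the 2 libraries farthest from the median it was -0.81. Both shares are large parts of the same total, so they cannot rise together without limit, and this alone favours a negative relation. The permutations ignore that limit, so their p-values do not show a relation beyond it.

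**Figure D1:**
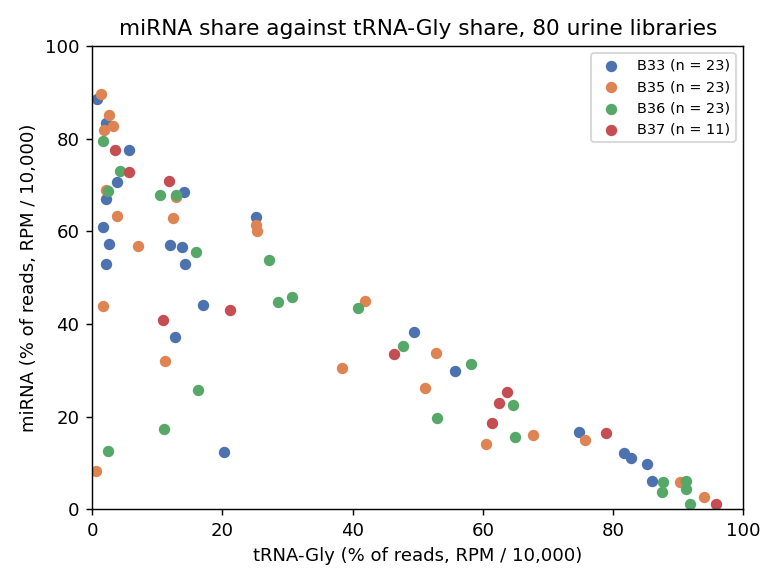
Share of reads that were miRNA (y axis, %) against the share that were tRNA-Gly (x axis, %) in 80 urine libraries, one point per library, coloured by title set. Libraries with tRNA-Gly near the maximum of 95.9% hold little miRNA, and r = -0.82.

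Among the fixed lists, that of kidney tubule miRNAs took the largest share of miRNA reads. The 12 listed members, among them the miR-30 family, miR-192, miR-194 and miR-204, took 31.9% ± 8.26 of miRNA reads (n = 80). Most of the list's RPM came from miR-30a-5p, and which cells released these miRNAs was not tested. miR-30a-5p was the most abundant miRNA at 74130 RPM (mean of the 4 set means, SD 56440 over libraries), followed by miR-21-5p at 59490 RPM (SD 50440), a miRNA raised in many injured tissues. miR-30d-5p stood at 17420 RPM (SD 13100), miR-30c-5p at 10360 RPM (SD 8229) and miR-30e-5p at 8488 RPM (SD 6597). miR-204-5p averaged 5037 RPM (SD 4473). The list of stromal and fibrosis miRNAs took 15% ± 6.12 of miRNA reads, and miR-21-5p gave most of it. That miRNA is made by many cell types. The other members of the list were lower, for example miR-29a-3p at 3094 RPM (mean over libraries, SD 2529) and miR-143-3p at 1511 RPM (mean over libraries, SD 3052). The let-7 family, which holds down growth-promoting transcripts in most tissues, took 9.38% ± 4.99, with let-7b-5p at 12140 RPM (SD 11050) and let-7a-5p at 11430 RPM (SD 10770). The miR-200 family, an epithelial group, took 6.18% ± 3.08, led by miR-200a-3p at 9136 RPM (SD 9241) and miR-141-3p at 6221 RPM (SD 9298). The HOX cluster miRNAs took 5.88% ± 2.7, with miR-10b-5p at 15550 RPM (SD 11900) and miR-10a-5p at 8971 RPM (SD 7345). The miR-17-92 cluster took 2.5% ± 1.11, with miR-92a-3p at 5755 RPM (SD 5701). The other abundant miRNAs were miR-99a-5p, let-7f-5p, miR-101-3p, miR-27b-3p, miR-26a-5p, miR-22-3p and miR-125b-5p, at 4795 to 7078 RPM.

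miRNAs of blood and of other tissues were present at lower and more uneven levels, given here as means over libraries. Erythroid miRNAs, led by miR-451a at 3536 RPM (SD 11450, median 321.3), took 1.79% ± 5.29 of miRNA reads, with a median of 0.311% and a range of 0.0322% to 34.0%. Leukocyte miRNAs took 0.53% ± 0.988, with miR-223-3p, a miRNA of neutrophils and monocytes, at 1174 RPM (SD 3906, median 138.9) and miR-146a-5p at 408.3 RPM (SD 470.5). Urothelial miRNAs took 1.49% ± 1.97, with miR-205-5p at 3184 RPM (SD 5845) and miR-203a-3p at 2754 RPM (SD 4592). Endothelial miR-126-3p stood at 673.3 RPM (SD 1038). Muscle and neural miRNAs took 0.165% ± 0.17, mostly miR-9-5p at 590.5 RPM (SD 624.9). The hepatocyte miRNA miR-122-5p averaged 39.57 RPM (SD 103.2) and reached 1 RPM in 51 of 80 libraries.

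**Figure D2:**
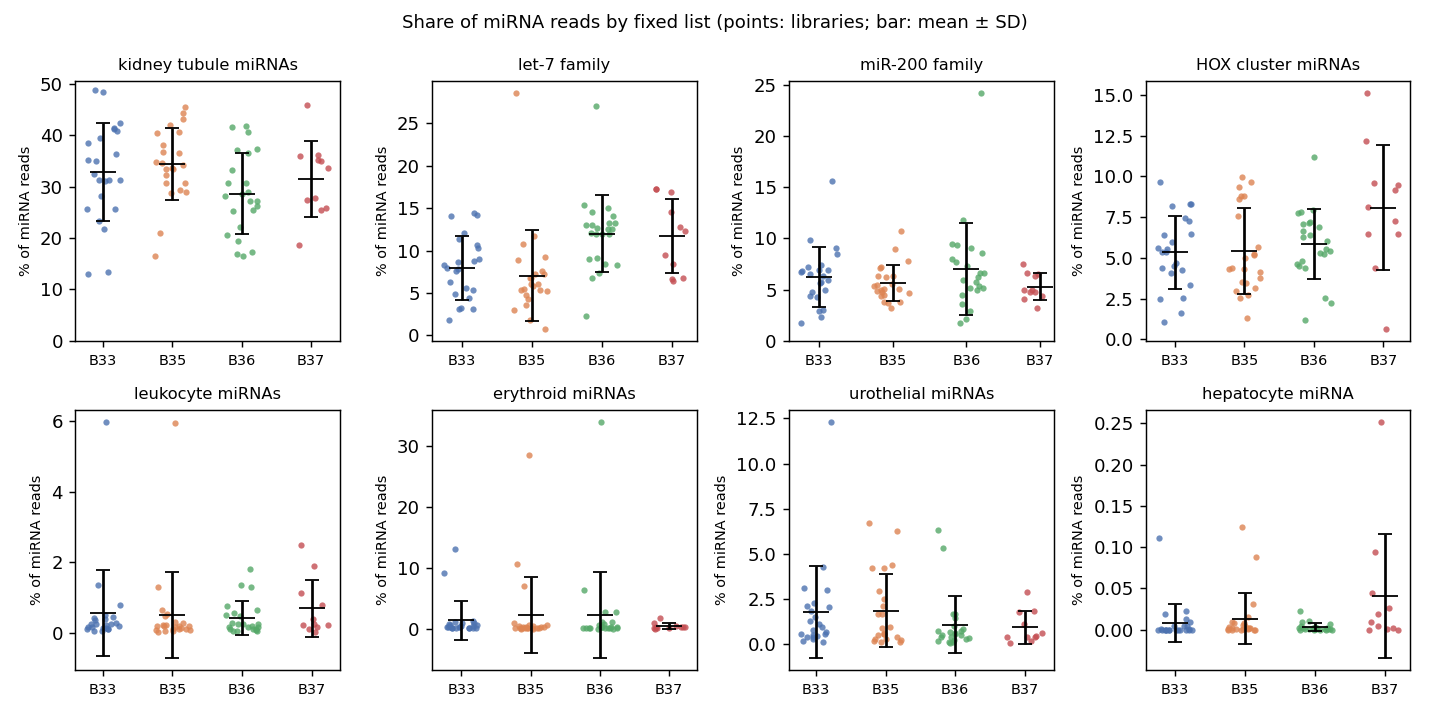
Share of miRNA reads (y axis, %) taken by 8 fixed miRNA lists in each title set (x axis), with libraries as points and the mean and SD as bars. Kidney tubule miRNAs took 32.8%, 34.3%, 28.6% and 31.5% on average in B33, B35, B36 and B37, while the erythroid share spread up to 34.0%.

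Among tRNA rows, tRNA-Val at 4807 RPM (SD 5906) and tRNA-Lys at 4214 RPM (SD 9565) came after Gly and Glu. tRNA-Arg, Tyr, Ala, Asp, Ile and Ser lay between 1236 and 1751 RPM. The most abundant piRNA row was hsa_piR_016658 at 1948 RPM (SD 1953), followed by hsa_piR_019825 at 382.6 RPM and hsa_piR_016659 at 231.6 RPM. hsa_piR_014620 and hsa_piR_000805 stood at 167.4 and 132.0 RPM.

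Among the fixed lists of the remaining genes, Y RNAs had the highest sum. RNY4, RNY5, RNY1 and RNY3, components of the Ro ribonucleoprotein, summed to 11930 RPM (SD 15100), or 17.2% ± 10.2 of reads in that table. RNY4 stood at 5386 RPM (SD 6484) and RNY5 at 4955 RPM (SD 9460). Pseudogene rows share reads with these genes, so the split between them is uncertain. Mitochondrial rRNAs summed to 595.4 RPM (SD 1374) and the 9 mitochondrial mRNAs to 174.5 RPM (SD 397.0). Vault, signal recognition particle and 7SK RNAs summed to 279.9 RPM (SD 256.2), led by VTRNA1-1 at 93.88 RPM (SD 134.3).

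The mRNAs of kidney and blood cells were near the detection limit. Of the 10 fixed mRNA lists for cell types, plasma proteins and injury, 9 had no row at 10 RPM or more in at least 11 libraries. Among proximal tubule mRNAs, GPX3, a secreted peroxidase, averaged 4.225 RPM (SD 13.26) and LRP2, the endocytic receptor megalin, 1.729 RPM (SD 3.88). The whole proximal tubule list summed to 17.26 RPM (SD 37.35, median 5.632), and 54 libraries held a member at 1 RPM or more. Summed over members, podocyte mRNAs averaged 2.295 RPM (SD 6.877), loop of Henle mRNAs 3.206 RPM (SD 8.571), distal tubule and collecting duct mRNAs 2.592 RPM (SD 5.925) and uroplakin mRNAs 1.901 RPM (SD 4.437). Neutrophil and monocyte mRNAs averaged 4.0 RPM (SD 16.48), lymphocyte mRNAs 0.2902 RPM (SD 1.797), haemoglobin mRNAs 0.9018 RPM (SD 2.975), plasma protein mRNAs 2.398 RPM (SD 5.55) and injury mRNAs 3.911 RPM (SD 9.36). Apart from the proximal tubule sum, these means lie below the 7.37 RPM that 3 reads give at the median depth. A library of that depth does not resolve such values, while deeper ones can. The protein-coding rows with the highest means were instead BICC1, an RNA-binding protein, at 2184 RPM (SD 3179), TIAL1 at 318.8 RPM (SD 560.6), SEMA3F at 306.5 RPM (SD 1923), GSG2 at 304.0 RPM (SD 859.1) and WDR74 at 196.3 RPM (SD 241.7). Of the 20 highest, 15 further rows ran from GPR126 at 53.5 RPM to ELAVL1, another RNA-binding protein, at 183.4 RPM. SEMA3F was at 1 RPM or more in 41 libraries, with a median of 1.335 RPM, so a minority of libraries carried its mean. Reads of a small RNA inside a gene are counted to that gene where the annotation allows it, and their sequences were not used here.

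Scores of kidney tubule, miR-200, stromal, leukocyte and erythroid miRNAs were compared across libraries to see which groups varied together. A score is the mean log2(RPM + 1) of a list's kept members. Of 12 pairs fixed beforehand, 7 had a list with no kept mRNA and could not be computed. p-values were adjusted over the 5 pairs computed. Kidney tubule miRNAs varied with the miR-200 family (Pearson r = 0.87, Spearman rho = 0.81, n = 80), stromal and fibrosis miRNAs with kidney tubule miRNAs (r = 0.79, rho = 0.73), leukocyte with erythroid miRNAs (r = 0.54, rho = 0.49) and kidney tubule with leukocyte miRNAs (r = 0.53, rho = 0.49). For each of these 4 pairs the permutation p was 1e-05, the smallest the permutations can give, and the adjusted p over 5 pairs was 1.3e-05. Without the 2 libraries farthest from the x median, r for these 4 pairs was 0.86, 0.74, 0.52 and 0.49 in the same order.

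Several of these relations changed when the share of all reads that were miRNA was taken out. After each library's miRNAs were rescaled to sum to 1000000, leukocyte and erythroid miRNAs still varied together (r = 0.4, adjusted p = 0.00055; rho = 0.32, adjusted p = 0.0085). Some members of these lists were low, for example erythroid miR-144-5p with a median of 0 RPM and leukocyte miR-150-5p with 1.288 RPM. Whether such members are seen can follow depth, which rescaling does not remove. Leaving out libraries under 100000 reads was not tried on rescaled scores. Kidney tubule and leukocyte miRNAs no longer passed the test (r = 0.2, adjusted p = 0.075; rho = -0.08, adjusted p = 0.51). For the miR-200 pair r was 0.63 (adjusted p = 0.0002) but rho was 0.23 (adjusted p = 0.072). For the stromal pair r was 0.35 (adjusted p = 0.0072) and rho was -0.07 (adjusted p = 0.51).

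Within sets, r on RPM as deposited was 0.87, 0.91, 0.87 and 0.94 for the miR-200 pair in B33, B35, B36 and B37. It was 0.84, 0.74, 0.78 and 0.8 for the stromal pair and 0.59, 0.61, 0.41 and 0.62 for the tubule and leukocyte pair, where the adjusted p in B36 was 0.064. For leukocyte and erythroid miRNAs it was 0.67, 0.26, 0.57 and 0.77, and in B35 the adjusted p was 0.22. A test with 10000 permutations for a difference in r between the 4 sets gave p = 0.32 for this pair (adjusted p = 0.84). For all 4 pairs, on RPM as deposited and rescaled, its adjusted p was 0.84 or 0.88, so no difference between sets was shown. After that rescaling, r for leukocyte and erythroid miRNAs was 0.55, 0.24, 0.42 and 0.34 in the 4 sets, with adjusted p of 0.025, 0.45, 0.096 and 0.39. The miR-200 pair then had r of 0.8, 0.32, -0.13 and 0.79 (adjusted p = 0.025, 0.35, 0.56 and 0.15), the stromal pair 0.66, -0.06, -0.38 and 0.4 (adjusted p = 0.04, 0.79, 0.096 and 0.39) and the tubule and leukocyte pair 0.38, 0.17, -0.38 and 0.26 (adjusted p = 0.098, 0.54, 0.096 and 0.51). In B33 rho was 0.29 for leukocyte and erythroid miRNAs, 0.28 for the miR-200 pair and 0.16 for the stromal pair (adjusted p = 0.5, 0.5 and 0.59), so the relations seen within sets on RPM as deposited mostly did not hold after rescaling.

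The title sets were compared to see how far libraries labelled with different sets differ, with B33, B35 and B36 as the background for B37. No miRNA among the 371 tested passed the F-test over the 4 sets (limma, Benjamini-Hochberg adjusted p under 0.05), while 38 had an unadjusted p under 0.05. The lowest p belonged to miR-1307-5p (adjusted p = 0.066), which averaged 1215 RPM in B33 (SD 1675), 2104 in B35 (SD 2465), 360.5 in B36 (SD 495.0) and 500.5 in B37 (SD 420.8). It was followed by miR-4454, miR-760 and miR-1299, with adjusted p of 0.1 each, and by miR-190a-3p at 0.13. The result depends on the scaling: 22 miRNAs passed after rescaling within the miRNA class, 18 with median-of-ratios factors and 33 with quantile normalization. On the 68 libraries whose whole reads were recovered, edgeR's quasi-likelihood test called 69 and limma 8.

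No miRNA differed between B37 and the mean of the other sets by limma, while 40 had an unadjusted p under 0.05, edgeR on the recovered reads called 25 (15 higher and 10 lower) and limma with library weights 21 (1 higher and 20 lower). miR-1299 averaged 37.32 RPM in B37 (SD 49.32) against 3.208 in B33 (SD 8.414), 15.38 in B35 (SD 46.99) and 6.825 in B36 (SD 17.84), a log2 difference of 2.34 ± 0.63 (SE; adjusted p = 0.1). It was called under the 3 other scalings (adjusted p = 0.029 rescaled, 0.013 with median-of-ratios factors and 0.00055 with quantile normalization). On RPM as deposited without libraries under 100000 reads, the log2 difference was 2.13 (adjusted p = 0.37). The median over all tested miRNAs was -0.54 (log2) with RPM as deposited, -0.49 after rescaling, -0.29 with median-of-ratios factors and -0.02 with quantile normalization. None of the 12 miRNA lists had a member that passed the test over all miRNAs. Adjusted over the list alone, 1 member of the miR-17-92 cluster, 1 of the muscle and neural miRNAs and the single hepatocyte miRNA passed. These were miR-19b-3p (log2 difference -1.58 ± 0.58, SE), miR-133a-3p (-2.01 ± 0.76) and miR-122-5p. The only list called by camera (adjusted p = 0.014) was the hepatocyte list, which is miR-122-5p by itself, so no correlation between members could be estimated for it. miR-122-5p averaged 116.7 RPM in B37 (SD 188.0) against 19.06 in B33 (SD 30.56), 52.68 in B35 (SD 128.3) and 10.09 in B36 (SD 17.64), a log2 difference of 1.97 ± 0.79 (SE). Its adjusted p over all miRNAs was 0.24, fry gave 0.24, and after rescaling camera gave 0.1. For the other 11 lists, camera's adjusted p ran from 0.15 for leukocyte miRNAs to 0.79, and with an estimated correlation the adjusted p ran from 0.77 to 0.88. Camera compares a list with all other miRNAs, so its direction was up for kidney tubule, miR-200, erythroid, endothelial, stromal and let-7 lists although their median log2 differences lay below 0. The HOX cluster list had a median of 0.11 and a mean of -0.06.

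Among the same-stem sets, 0 miRNAs differed between B35 and B33 and 0 between B36 and B33 by limma, with 15 and 29 at an unadjusted p under 0.05. Between B36 and B35, miR-1307-5p fell by 2.55 on the log2 scale (adjusted p = 0.023), but with a pseudocount of 0.1 and with no filter 0 miRNAs were called. After rescaling, 15 miRNAs were higher and 4 lower in B36 than in B35, with median-of-ratios factors 16 and 3, and with quantile normalization 23 and 10.

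tRNA-Glu differed among the sets (F-test adjusted p = 0.025), the only tRNA row of 24 to do so. It averaged 50370 RPM in B36 (SD 27280) against 23230 in B33 (SD 12260), 27310 in B35 (SD 22290) and 36940 in B37 (SD 34240). The call ended under all 3 other scalings, as 0 tRNA rows passed after rescaling within the class and with median-of-ratios factors, and the 1 that passed with quantile normalization was another row. Without libraries under 100000 reads, 0 passed. No tRNA row passed the test of B37 against the other sets, while 11 had an unadjusted p under 0.05. tRNA-Ala had a log2 difference of -1.79 ± 0.63 (SE) and tRNA-Gly of 0.78 ± 0.64 (adjusted p = 0.076 and 0.31). Of 19 piRNA rows, 6 passed the F-test. hsa_piR_014620 averaged 360.5 RPM in B35 against 107.4 in B33, 67.47 in B36 and 134.1 in B37 (adjusted p = 0.026). hsa_piR_004153 had its highest median in B36, at 25.84 RPM (mean 33.77, SD 26.68), against 10.71 in B33 (mean 15.83, SD 24.2), 5.819 in B35 (mean 14.48, SD 20.11) and 15.72 in B37, where the mean of 43.58 had an SD of 92.19 (adjusted p = 0.026). The other 4 rows, hsa_piR_001311, hsa_piR_001312, hsa_piR_018569 and hsa_piR_018570, had nearly equal values. These 4 and hsa_piR_004153 were chosen after their values were seen. No piRNA row passed in B37 against the other sets, and 0 had an unadjusted p under 0.05. The 6 calls ended with a pseudocount of 0.1, after rescaling within the class and without libraries under 100000 reads, where 0 piRNA rows passed the F-test each time.

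Some gene rows other than miRNA, tRNA and piRNA also differed between sets. Of 469 rows, 34 passed the F-test, and 12 were lower and 0 higher in B37 than in the other sets. TIAL1, an RNA-binding protein of stress granules, averaged 30.27 RPM in B37 (SD 62.07, n = 11) against 743.6 in B33 (SD 747.9), 261.6 in B35 (SD 469.3) and 239.8 in B36 (SD 337.6). Its log2 difference was -4.67 ± 0.71 (SE; limma adjusted p = 9e-07), and 10 of 11 B37 libraries lay below the median of the others. GSG2, a histone kinase, fell by 2.93 on the log2 scale (SE 0.74, adjusted p = 0.014), although it also differed among the same-stem sets, at 1009 RPM in B33 against 98.66 in B35 and 78.98 in B36. FAXC fell by 2.49 (adjusted p = 0.017) and TOP2B, a DNA topoisomerase, by 2.41 (adjusted p = 0.034). CRKL, an adaptor of tyrosine kinase signalling, fell by 1.9 and UBXN2A by 1.89 (adjusted p = 0.034 each). Set medians of FAXC were 2.004, 5.816, 4.953 and 0 RPM in B33, B35, B36 and B37. Those of UBXN2A were 1.123, 5.979, 4.727 and 0 RPM in the same order. All of these lie below the 7.37 RPM that 3 reads give at the median depth. TOP2B had medians of 5.525, 22.25, 7.17 and 0.0182 RPM. For CRKL the higher level was that of B36, at 108.1 RPM against 3.677 in B33 and 2.607 in B35. The 12 rows included 4 of TIAL1 under different biotypes and AC023050.1 and AC034205.1, whose values were nearly equal, so they stand for fewer transcripts. The antisense row AC002310.12 was also among them, and reads of antisense partners are uncertain here. Of the fixed lists, none of 4 Y RNAs, 8 vault and signal recognition rows, 9 mitochondrial mRNAs or 2 mitochondrial rRNAs passed. RNY5 averaged 12580 RPM in B37 (SD 22800) against 3506, 2881 and 4834 RPM in B33, B35 and B36 (adjusted p = 0.48). The split of calls moved with the scaling, to 4 higher and 27 lower with median-of-ratios factors and 45 higher and 20 lower with quantile normalization. Without set B36, 7 rows passed, and CRKL, whose log2 difference shrank to -0.7 (adjusted p = 0.44), was not among them. UBXN2A and TOP2B did not pass either, but their log2 differences were -1.76 and -2.63 (adjusted p = 0.086 and 0.053). GSG2 did not pass without B33 (log2 difference -1.82, adjusted p = 0.2), nor TOP2B without B35 (log2 difference -1.92, adjusted p = 0.2). Without libraries under 100000 reads, GSG2, TOP2B and CRKL did not pass, with log2 differences of -2.42, -1.64 and -1.86 on fewer libraries (adjusted p = 0.064, 0.19 and 0.11). With a pseudocount of 10, FAXC, TOP2B, CRKL and UBXN2A did not (adjusted p = 0.069, 0.099, 0.11 and 0.067), and with no filter TIAL1 alone of these 6 genes passed. TIAL1 stayed called in each of these settings.

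**Figure D3:**
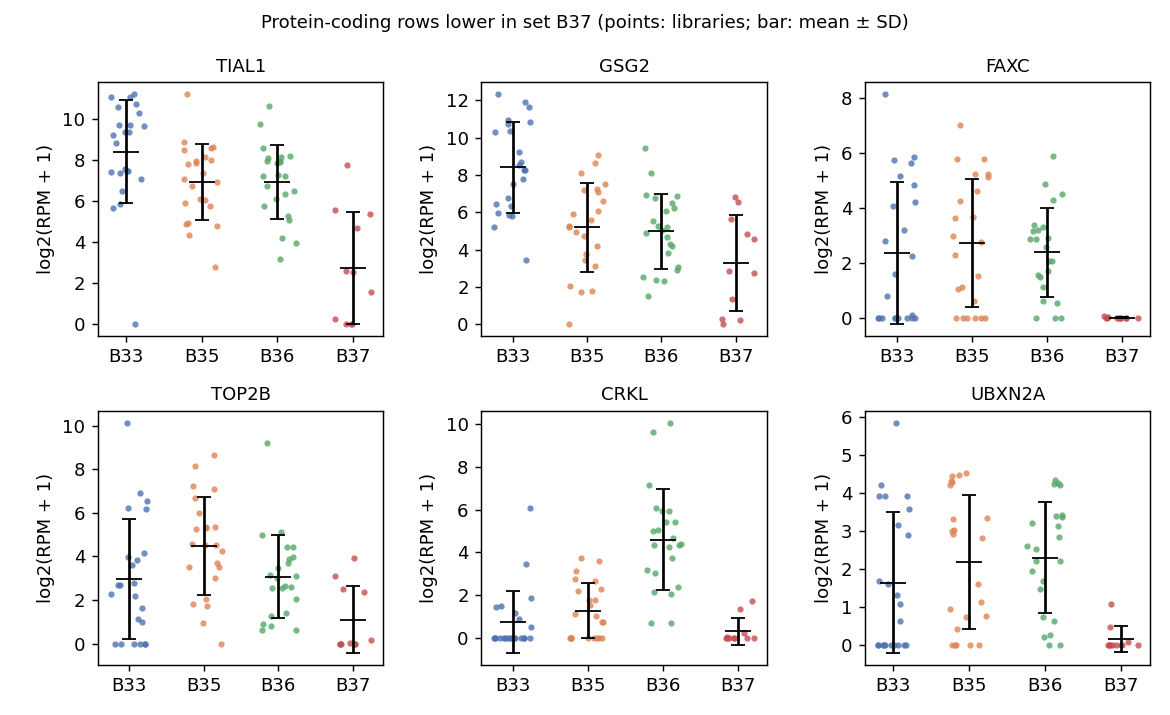
Levels of 6 protein-coding rows lower in B37, as log2(RPM + 1) on the y axis, in each title set on the x axis, with libraries as points and the mean and SD as bars. TIAL1 has the largest difference, -4.67 on the log2 scale, while GSG2 is highest in B33 and CRKL in B36.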

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

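Circular RNAs entered no comparison, since none of the 36 rows reached 10 RPM in 11 libraries, but 16 of 80 libraries held more than 3 circular RNA reads, above the limit that a count of 0 allows. The libraries were 5 of B33, 7 of B35, 3 of B36 and 1 of B37. The row seen most often, hsa_circ_000353, was above 0 in 19 libraries and averaged 2.62 RPM. No control samples were among those used here, and no explanation was tested.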

How the results depend on the processing

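Added after seeing the data were the settings without libraries under 100000 reads, with log10 reads as a covariate and with limma on the 68 libraries. Added too was rescaling for the miRNA lists, where the count of 1 of 12 became 0. Estimating the correlation does not test that list, which has 1 member. The class composition and the most abundant RNAs moved by less than their SD when medians were used. This does not test their stability. A mean and a median of the same values never differ by more than the SD. SEMA3F, for example, went from 306.5 RPM to a median of 1.335 RPM. Where a count moved, the cause was tested only for the miRNAs called after rescaling and the gene rows lower in B37. miRNAs differing among the 4 sets numbered 0, against 1 with a pseudocount of 10, 1 with the 40-library filter, 22 rescaled, 18 with median-of-ratios factors, 33 with quantile normalization, 1 with the replicate block, 4 without trend, 22 with library weights, 8 with limma on 68 libraries and 69 with edgeR. In B37 against the others, miRNAs numbered 0, against 2 rescaled, 2 with median-of-ratios factors, 2 with quantile normalization, 21 with library weights, 1 without set B33, 2 with limma on 68 libraries and 25 with edgeR. For B35 against B33 the count of 0 became 1 with a pseudocount of 10, 2 without a filter, 1 rescaled, 2 with median-of-ratios factors, 9 with quantile normalization, 1 with the replicate block and 1 without trend. For B36 against B33 the count of 0 became 1 with a pseudocount of 10, 4 rescaled, 6 with median-of-ratios factors and 4 with quantile normalization. For B36 against B35 the count of 1 became 0 with a pseudocount of 0.1, 2 with 10, 0 without a filter, 2 with the 40-library filter, 19 rescaled, 19 with median-of-ratios factors, 33 with quantile normalization and 2 without trend. tRNA rows among the sets numbered 1, against 0 rescaled, 0 with median-of-ratios factors, 4 with library weights and 0 without libraries under 100000 reads, and in B37 0 became 3 with library weights. piRNA rows among the sets numbered 6, against 0 with a pseudocount of 0.1, 1 without a filter, 2 with the 40-library filter, 0 rescaled, 2 with quantile normalization and 0 without libraries under 100000 reads, and in B37 0 became 1 without a filter. Median-of-ratios factors could not be had for piRNAs, since a library held none of the rows they rest on, and edgeR was not run for tRNAs, piRNAs and gene rows, whose columns were not recovered as whole reads. Gene rows among the sets numbered 34, against 54 with a pseudocount of 10, 17 without a filter, 15 with the 40-library filter, 91 rescaled, 102 with median-of-ratios factors, 110 with quantile normalization, 93 with library weights and 19 without libraries under 100000 reads. Gene rows in B37 numbered 12, against 5 without a filter, 20 rescaled, 31 with median-of-ratios factors, 65 with quantile normalization, 54 with library weights and 7 without set B36, and all 12 were among those called under rescaling, median-of-ratios factors and quantile normalization. For the correlations, kidney tubule with leukocyte miRNAs was 0.2 after rescaling, no longer past the threshold.

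The replicate block uses the adapter number, which marks a shared 3′ adapter and not a shared person. Of 99 pairs of libraries with the same number, 44 had a correlation of deviations over 0.1, the median was 0.08 against -0.01 for other pairs, and 14 of 80 libraries correlated best with a library of their own number, against 3.4 expected by chance. This hints that libraries with the same adapter resemble each other slightly. B37 holds only adapter numbers 1 to 11, while the other sets run up to 24. The B37 contrast without the block is therefore partly confounded with the adapter. The numbers were not taken to pair the samples, since only 44 of the 99 pairs passed 0.1. With the block, miRNAs among the sets numbered 1, gene rows among the sets 29, gene rows in B37 10 (8 of the main 12, without GSG2, FAXC and TOP2B at adjusted p = 0.091, 0.12 and 0.091), piRNA rows among the sets 6, tRNA rows among the sets 1, miRNAs of B35 against B33 1, miRNAs of B36 against B35 1, and the lists 1, and the other counts stayed at 0. Depth limits the rest: 19 libraries held under 100000 reads.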

Other observations

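Of the tests below, those on the miRNAs called after rescaling, on the scaling of the gene rows, on their differences among B33, B35 and B36, and on tRNA-Gly against reads were chosen after the result was seen. With each library's miRNAs rescaled to sum to 1000000, 2 of the 9 let-7 members passed the test over the sets. let-7f-5p averaged 14030 RPM of miRNA reads in B33, 8233 in B35, 21710 in B36 and 21440 in B37 (limma F-test adjusted p = 2.6e-06), and let-7a-5p 22850, 16560, 35780 and 36340 (adjusted p = 0.0014). miR-19b-3p of the miR-17-92 cluster averaged 7016, 10100, 5519 and 2420 (adjusted p = 0.0014), and was lower in B37 than in the other sets (log2 difference -1.39, adjusted p = 0.0041). The other miRNA called in B37 was miR-1299, which was higher there (log2 difference 3.07, adjusted p = 0.029). Its medians on RPM as deposited were 0, 0, 2.106 and 13.21 in B33, B35, B36 and B37, near the detection limit. On rescaled values without libraries under 100000 reads, miR-1299 was not among the miRNAs called over the sets. The tubule miRNAs miR-30e-5p (adjusted p = 0.0039) and miR-30c-5p (adjusted p = 0.0061) went apart, with miR-30e-5p highest in B35 at 25970 and miR-30c-5p lowest there at 18700. These members of fixed lists were picked out after their values were seen.

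The 22 miRNAs called among the sets after rescaling, against 0 on RPM as deposited, may have been hidden by changes in the miRNA share that move all miRNAs together. Over all 371 tested miRNAs, the SD within sets was smaller after rescaling in 34.8% of them, and the median SD rose from 2.18 to 2.41. This cannot decide the question. Rescaling raises every value above 0 and leaves values of 0 in place, which by itself can widen the spread of low miRNAs. Over the 22 called miRNAs the SD was smaller in 50%, and its median rose from 1.96 to 2.09. With as many falling as rising among these 22, the explanation stays open. Shallow libraries are argued against, since 47 miRNAs were called on rescaled values without libraries under 100000 reads, 17 of them among the 22. No biological explanation was tested, since the labels do not say what the sets stand for.

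The 12 gene rows lower in B37 could come from scaling, from shallow libraries or from a difference between library batches. Scaling is argued against, since 12 of 12 rows were called after rescaling and with median-of-ratios factors. Without libraries under 100000 reads, the median log2 difference over the 12 rows was -2.26, against -2.5 with all libraries, and 6 of the 12 stayed called. For TIAL1, which gives 4 of the rows, shallow libraries are argued against as the whole cause. It stayed called, and its medians were 589.8, 131.5 and 147 RPM in B33, B35 and B36 against 4.852 in B37. For rows with medians near the detection limit, such as FAXC and UBXN2A, the cut cannot decide. Libraries above it can also miss such rows. A batch difference cannot be told apart from the title set, since each set may have been processed together, and 16 gene rows differed among B33, B35 and B36, which share a title stem, 2 of them among the 12.

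Libraries with more reads may hold a larger tRNA-Gly share. Pooled Spearman rho was 0.26 (permutation p = 0.021) and Pearson r = 0.32 (p = 0.0038, adjusted p = 0.0038 over 2 relations). Without the 2 libraries farthest from the median, r was 0.27, and without libraries under 100000 reads rho no longer passed the test (0.23, p = 0.078), while r was 0.34. The relation passed the test within B36 (rho = 0.56, p = 0.0057) and in no other set, with rho of 0.38 in B33, -0.02 in B35 and 0.23 in B37, so it stays open.

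In 100 splits of the libraries into sets of the same sizes, the real one included, chance can be excluded at 0.05 for each count taken alone for the 34 gene rows among the sets (3 splits as large, highest other 169), the 12 gene rows in B37 (2 splits, highest other 114), the 6 piRNA rows among the sets (2 splits, highest other 15) and the 1 tRNA row (3 splits, highest other 1). Adjusted over the 12 counts, the share of such splits was 0.09 for each, which is not under 0.05. The 12 include the counts of 0, for which every split had to be as large, and this raises the adjusted shares. The adjustment therefore cannot decide whether chance is excluded for these counts. Chance cannot be excluded for the 1 miRNA of B36 against B35 (8 splits, highest other 9) or the 1 list in B37 (61 splits, highest other 6). For the counts of 0, all 100 splits were as large, with highest others of 80 for miRNAs among the sets, 87 for miRNAs in B37, 53 for B35 against B33, 76 for B36 against B33, 2 for tRNA rows in B37 and 2 for piRNA rows in B37. Some splits called many more features than the real one. This may point to a structure among the libraries other than the sets, but features that vary together could give it too. Listed miRNAs do vary together, with estimated correlations of 0.206 to 0.742 within the lists of more than 1 member. Whether either gave these counts was not tested.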
